A study of Mus musculus with 8 samples.

How the data were processed

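RNA-seq was measured in 8 libraries of T-ALL blasts (T cell acute lymphoblastic leukaemia cells) sorted from the blood of mice carrying the Vav-CRE transgene, which drives recombination in blood-forming cells. The labels put 4 libraries in a control group with wild-type Kdm6b and 4 in a Kdm6b-KO group. Nothing in the labels says whether the 4 libraries of a group come from separate mice. In the sample titles, the libraries of a group share a number and differ by a letter, and the meaning of neither is given. A shared origin of the libraries within each group is therefore possible. The p-values therefore measure the spread between these libraries, which may be partly technical. Per the labels' protocols, RNA was taken with the NucleoSpin RNA XS kit and libraries were made with the SMARTer Ultra Low RNA kit. The submitters' processing notes name the aligner STAR (version 2.7.3a), the Partek software (version 10.0.22.0524) and the genome build mm10. The gene counter, its strand setting and the annotation release are not given in the sources used here.

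The authors deposited a table of CPM, read counts scaled to the same sum in every library, for 20888 genes in all 8 libraries. Each deposited CPM value has 0.0001 added to it, and this constant was subtracted here before any other step. A deposited list of 218 genes gives the authors' signed linear fold of control over knockout, with the mean CPM per group. Per the deposited description sheet, its genes passed a p-value, a false discovery rate and a fold threshold, and the statistical model is not given. The CPM values in that list did not differ from those in the table of all genes. The 19 symbols that look like calendar dates were kept as they stand.

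Depth was worked out from the step between low CPM values, which is what 1 read is worth. It gave 18263010, 19226530, 19106680 and 22070880 reads for control replicates 1 to 4 and 16215760, 14017980, 18244220 and 14183580 reads for knockout-labelled replicates 1 to 4, so every knockout-labelled library was shallower than every control library, by little for control replicate 1 and knockout-labelled replicate 3. Between 66.2% and 67.8% of the values in a library were whole multiples of 1 read within 0.02 reads. The others were fractional, so whole reads were not recovered and no count model was run. A count of 3 reads corresponds to between 0.136 and 0.214 CPM, and a level under this floor was read as not detectable at this depth. The floor covers counting error only.

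Genes with at least 1 CPM in at least 4 of the 8 libraries were kept, which left 13840 genes. The test was limma (version 3.58.1, in R 4.3.3) on log2(CPM + 1), with lmFit and eBayes with a mean-variance trend, as knockout-labelled minus control, two-sided. P-values were adjusted by Benjamini-Hochberg over the 13840 genes, and a gene was called at an adjusted p below 0.05. All log2 changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. Errors of levels are standard deviations (SD) over the 4 libraries of a group, and errors of log2 changes are limma standard errors (SE). For Kdm6b, an exact two-sided permutation test over all 70 assignments was added, which cannot give a p below 0.0286.

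Before the data were examined, 35 gene lists were written down: pathways, markers of other blood cells, and signs of quality and sex. The 33 lists with at least 5 tested members were tested with camera from limma at a preset correlation between genes of 0.01, two-sided, and adjusted by Benjamini-Hochberg over the 33 lists. Beside it stand camera with a correlation estimated from the data, and fry. In fry, the directional p tests whether the genes of a list move, on balance, one way, and the mixed p whether they change in either direction. A list score is the mean log2(CPM + 1) of the tested members in a library. Another 5 lists were written after the called genes had been seen.

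The genes named were fixed by a rule. It takes Kdm6b and the 10 highest and 10 lowest log2 changes among called genes with no overlap between the groups and a mean of at least 5 CPM, leaving out predicted loci and receptor segments. It adds up to 4 called members of each pathway list, or the 2 with the lowest p where none was called. From each marker and quality list it takes the 2 most abundant members and up to 2 called members. It ends with the 3 highest and 3 lowest folds of the deposited list. This gave 89 genes, of which 2 are not reported here. Others are named as chosen after their values were seen. Of the tested genes, 98.3% had coordinates by symbol in the GENCODE vM21 annotation of mm10, which may differ from the annotation used by the authors. In it, exons of 26 of the 89 named genes overlap a gene on the opposite strand, among them Jun, Fen1, Cdc45, Dnaja1, Bcl2 and Ppp1r15a. Without a stated strand setting their reads cannot be told apart from those of the other gene, so these values are uncertain.

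The gene and list tests were checked on simulated libraries drawn from each gene's mean level and variance and the estimated depths. With 200 of 13840 genes changed, the test of genes changed in Kdm6b-KO blasts recovered 14.5% of 1.5-fold, 40.0% of 2-fold and 77.9% of 4-fold changes, with 8 false calls. 1 list moved by 1.5-fold was recovered and 0 other lists were called. The simulated genes were drawn independently, while the estimated correlation between the real mitosis genes was 0.89. The simulation therefore does not check the list test for correlated genes.

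The alternatives fixed at the same time as the lists were pseudocounts of 0.1, 0.5 and 5, no filter, a mean of at least 5 CPM, median-ratio scaling, quantile normalization, eBayes without trend and with the robust option, array weights, a replicate block, and leaving out each library. Others were an adjusted p under 0.1, an estimated correlation and fry for the lists, and Trav in place of Trbv receptor segments. Count models had been planned only if whole reads could be recovered. Chosen after the data were seen were a test without the X and Y chromosomes, a test without both libraries numbered 4, and the count of called members of 3 lists. For the splits, all 35 ways of dividing the 8 libraries into 4 and 4 were fitted. The tests of explanations were run in Python (version 3.11.15) with numpy (version 2.4.6) and pandas (version 2.3.3), and figures were drawn with matplotlib (version 3.10.9).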

Results

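The study compared blasts of T cell acute lymphoblastic leukaemia (T-ALL), sorted from mouse blood, between controls and mice with the histone demethylase gene Kdm6b deleted in blood-forming cells. The series title ties KDM6B to stress from the oncogene NOTCH1, a receptor gene often mutated in T-ALL. Gene expression was measured by RNA-seq in 4 control libraries and 4 libraries labelled Kdm6b knockout. Estimated depths were 18263010 to 22070880 reads in the controls and 14017980 to 18244220 reads in the knockout-labelled libraries.

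Kdm6b itself, which encodes an enzyme that removes methyl groups from lysine 27 of histone H3, was not lower in the knockout-labelled libraries. It lies on chromosome 11 from 69398508 to 69413675 (mm10). Its level was 514 ± 135 CPM (SD, n = 4) in the controls and 587 ± 92.2 CPM (SD, n = 4) in the knockout-labelled libraries. The log2 change was 0.22 ± 0.21 (SE), with a 95% interval from -0.23 to 0.67. The exact two-sided permutation p was 0.514, and the limma adjusted p was 0.599. A gene-level value holds reads from exons outside any deleted part, so it checks neither the labels nor the deletion. An antisense gene, Kdm6bos, overlaps Kdm6b on the opposite strand. For these reasons the second group is called knockout-labelled throughout, and every direction given here rests on the labels.

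The groups differed in every sex-linked gene of the list fixed for it. Xist, the RNA that silences one X chromosome in female cells, was at 0.325 ± 0.381 CPM in the controls and 386 ± 85.2 CPM in the knockout-labelled libraries (SD, n = 4 each). The Y-linked genes showed the opposite. Ddx3y, an RNA helicase gene, was at 168 ± 34.7 and 0.221 ± 0.220 CPM in controls and knockout-labelled libraries, the translation factor gene Eif2s3y at 128 ± 12.0 and 0.369 ± 0.399 CPM, the histone demethylase gene Kdm5d at 39.8 ± 11.4 and 0.0711 ± 0.101 CPM, and Uty, the Y-linked relative of Kdm6b, at 73.1 ± 15.6 and 0.277 ± 0.243 CPM. Their limma adjusted p ran from 4.55e-09 for Xist and Ddx3y to 4.36e-07 for Kdm5d, and the list had a camera adjusted p of 1.45e-07, or adjusted p = 0.101 with an estimated correlation. All 4 controls carried Y-linked transcripts and all 4 knockout-labelled libraries carried Xist, so sex and label cannot be told apart in these libraries. The low means moved by over 1.5 times with 1 library left out: Xist was at 0.156 CPM and Tsix at 0.0881 CPM in the controls without control replicate 4. In the knockout-labelled libraries Ddx3y was at 0.112 CPM without replicate 3, and Eif2s3y, Uty and Kdm5d were at 0.230, 0.179 and 0.0235 CPM without replicate 2. Tsix, antisense to Xist, was at 0.606 ± 1.04 and 121 ± 42.9 CPM, and without a stated strand setting its reads cannot be separated from those of Xist. Kdm6a, the X-linked relative of Kdm6b, rose from 48.2 ± 8.22 to 80.4 ± 12.4 CPM (log2 change 0.73 ± 0.16, limma adjusted p = 0.0360), with no overlap between the groups. Its call was lost without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 3, with adjusted p up to 0.120.

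**Figure D1:**
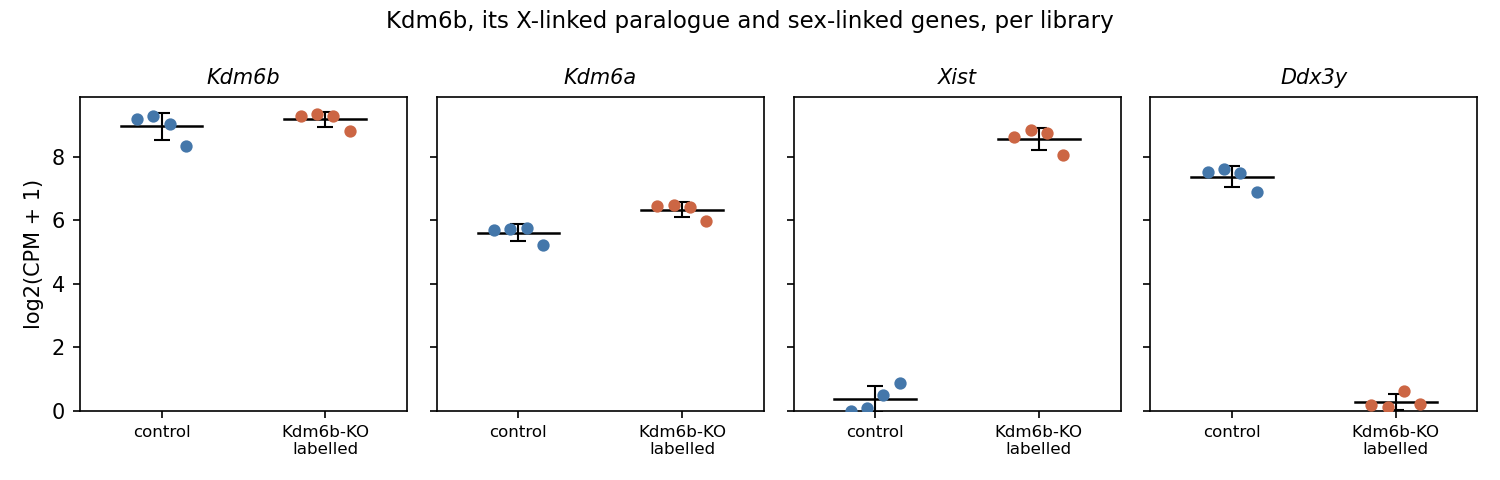
Levels of Kdm6b, Kdm6a, Xist and Ddx3y as log2(CPM + 1) on the vertical axis for the 4 control and 4 knockout-labelled libraries; each point is a library, the long bar is the mean and the whiskers are the SD. Kdm6b overlaps between the groups, while Xist is high in the 4 knockout-labelled libraries and Ddx3y in the 4 controls.

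Across all genes, more fell than rose in the knockout-labelled libraries. Of 13840 genes tested, limma with Benjamini-Hochberg adjustment called 488, of which 321 were lower (65.8%) and 167 higher. At least 2-fold changes were called for 289 genes, 204 lower and 85 higher. At an unadjusted p below 0.05 there were 2677 genes. The groups did not overlap for 13.2% of genes, against 2.86% by chance. The X and Y chromosomes held 17 of the calls and the other chromosomes 471. Under quantile normalization 188 calls were higher and 237 lower (55.8% lower). The count of called genes was 96 without control replicate 1, 178 without control replicate 3, and 150, 81 and 170 without knockout-labelled replicates 1, 2 and 4, and the count at 2-fold or more was 87, 158, 134, 71 and 116 in the same order. Array weights raised the first count to 1313, and a pseudocount of 5 lowered the second to 165.

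**Figure D2:**
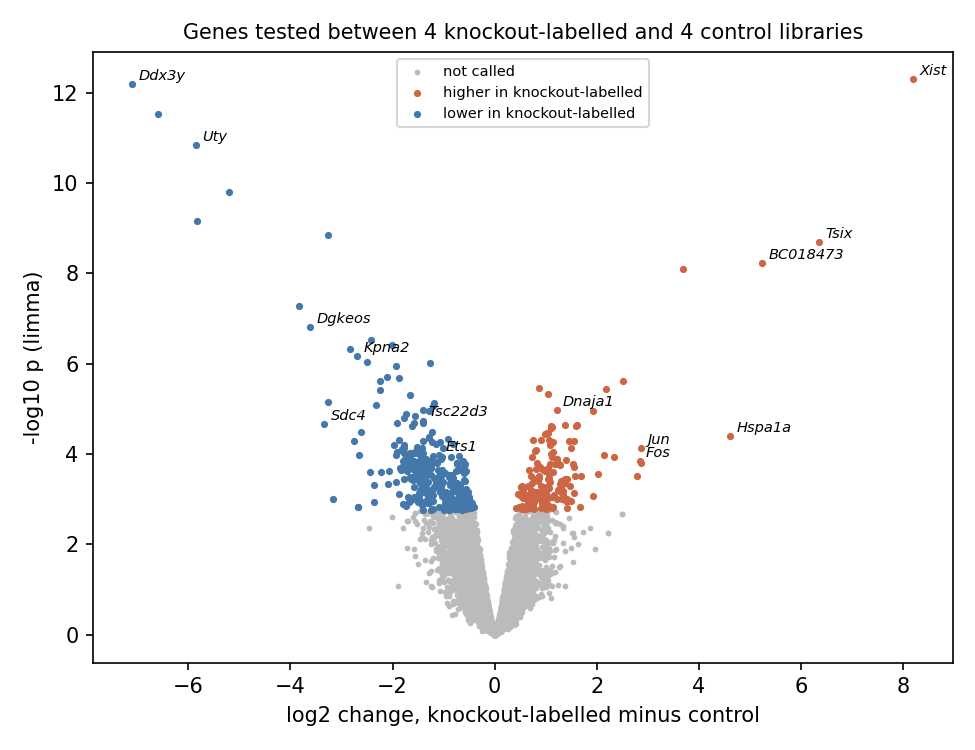
Log2 change, knockout-labelled minus control, on the horizontal axis against the limma p as -log10 on the vertical axis, with 1 point per tested gene. Blue points are the 321 genes called lower and orange points the 167 called higher in the knockout-labelled libraries, and grey points were not called.

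Outside the sex-linked genes, the named genes with the highest changes included chaperone and transcription factor genes. Jun and Fos encode subunits of the transcription factor AP-1. Jun rose from 17.4 ± 2.37 to 171 ± 118 CPM (log2 change 2.87 ± 0.48, limma adjusted p = 0.0126) and Fos from 4.82 ± 1.0 to 54.1 ± 43.2 CPM (log2 change 2.84 ± 0.51, adjusted p = 0.0163). The heat shock protein gene Hspa1a was at 0.125 ± 0.234 CPM in the controls, a mean under the floor of detection, and at 44.8 ± 42.1 CPM in the knockout-labelled libraries (adjusted p = 0.00953), a value made uncertain by its near-identical copy Hspa1b. Without control replicate 2 the control mean of Hspa1a was 0.00839 CPM. The knockout-labelled libraries were uneven in these genes, with replicates 1 and 2 above replicates 3 and 4. Jun was at 274 and 268 against 98.7 and 43.1 CPM, Fos at 105 and 75.5 against 20.8 and 15.4 CPM and Hspa1a at 86.0 and 76.0 against 12.0 and 5.24 CPM, all above the highest control. Gbp2b, of the interferon-inducible guanylate-binding family, rose from 5.75 ± 3.90 to 38.0 ± 16.3 CPM, and Tbc1d2, which encodes a GTPase-activating protein for Rab proteins, from 9.04 ± 4.63 to 53.1 ± 13.6 CPM. Hey1, a transcription factor gene downstream of Notch receptors, rose from 7.13 ± 3.56 to 35.8 ± 17.5 CPM, the microsomal glutathione transferase gene Mgst1 from 9.59 ± 4.74 to 42.0 ± 23.6 CPM, and Cdk5rap1, which encodes a tRNA-modifying enzyme, from 7.88 ± 1.59 to 34.7 ± 16.3 CPM. The call of Jun was lost without knockout-labelled replicate 2 (adjusted p = 0.0507), and that of Fos without control replicate 1 or knockout-labelled replicate 2 (adjusted p up to 0.0663). Gbp2b lost it without knockout-labelled replicate 1, 2, 3 or 4 (up to 0.0754), Hey1 without control replicate 1 or knockout-labelled replicate 2 or 4 (up to 0.0615) and Mgst1 without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 4 (up to 0.0599).

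Outside the Y chromosome, the antisense gene Dgkeos had the lowest change among the named genes. It fell from 29.4 ± 12.7 to 1.30 ± 0.311 CPM (log2 change -3.61 ± 0.32, limma adjusted p = 0.000177), and it overlaps Dgke on the opposite strand. Sdc4, a cell surface proteoglycan gene, fell from 87.0 ± 35.2 to 9.25 ± 7.62 CPM (log2 change -3.34 ± 0.48, limma adjusted p = 0.00680). Kpna2, an importin gene, fell from 54.6 ± 17.5 to 7.53 ± 2.63 CPM (log2 change -2.70 ± 0.28, adjusted p = 0.000586). The cytochrome b561 gene Cyb561 fell from 19.9 ± 16.4 to 0.838 ± 0.511 CPM, the linker histone gene H1f0 from 21.8 ± 15.4 to 2.35 ± 1.46 CPM and the scavenger receptor family gene Cd163l1 from 28.6 ± 34.5 to 1.69 ± 2.39 CPM. Control replicate 4 had the highest control value of the last 3 genes, and without it their control means were 11.8, 14.5 and 11.6 CPM. In the knockout-labelled libraries the mean of Cd163l1 was 0.543 CPM without replicate 4 and that of Sdc4 5.68 CPM without replicate 3. Cd163l1 lost its call without control replicate 1 or knockout-labelled replicate 1, 2 or 3 (adjusted p up to 0.124) and H1f0 without knockout-labelled replicate 2 or 4 (up to 0.0518).

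Genes of mitosis fell together. Of the 26 members tested, 23 fell, 0 rose and 3 were not called, and 26 fell when adjusted over the list alone (median log2 change -1.49). Kif11, which encodes a motor protein of the spindle, fell from 105 ± 38.5 to 29.8 ± 5.80 CPM (log2 change -1.73 ± 0.24, limma adjusted p = 0.00479). Hmmr, a spindle assembly gene, fell from 57.0 ± 20.6 to 15.7 ± 5.71 CPM, the mitotic kinase gene Nek2 from 34.8 ± 10.4 to 11.5 ± 3.82 CPM, and Ube2c, a ubiquitin-conjugating enzyme gene of the anaphase-promoting complex, from 133 ± 50.8 to 46.9 ± 7.80 CPM. The list was lower by camera (adjusted p = 2.89e-24, or adjusted p = 0.404 with an estimated correlation). Called members numbered 4 without control replicate 1, 14 without control replicate 3, and 7, 1 and 6 without knockout-labelled replicates 1, 2 and 4. With each single library left out the median stayed between -1.73 and -1.23. Hmmr lost its call without control replicate 1 or knockout-labelled replicate 2, and Nek2 and Ube2c without knockout-labelled replicate 2 (adjusted p up to 0.0575).

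The DNA replication, DNA damage repair and CDK inhibitor lists were lower too, though CDK inhibitors act against the kinases that drive division. In the DNA replication list 4 of 26 members fell, or 22 adjusted over the list alone (median log2 change -0.81). Over all genes, the ribonucleotide reductase gene Rrm2 fell from 501 ± 163 to 191 ± 60.7 CPM, the flap endonuclease gene Fen1 from 209 ± 50.8 to 126 ± 10.8 CPM, the DNA polymerase gene Pole from 26.4 ± 14.4 to 7.54 ± 2.95 CPM and Cdc45, a gene of the replicative helicase, from 31.6 ± 16.4 to 12.1 ± 4.48 CPM. The camera adjusted p was 1.92e-12, or adjusted p = 0.439 with an estimated correlation. In the DNA damage repair list 1 of 22 fell, the histone gene H2ax, from 208 ± 80.9 to 91.7 ± 15.2 CPM. Adjusted over the list alone, 12 fell (list median -0.47, camera adjusted p = 1.84e-05, or adjusted p = 0.598 with an estimated correlation). Among CDK inhibitors 1 of 7 fell, and 1 adjusted over the list alone. It was Cdkn2c, which encodes an inhibitor of CDK4 and CDK6, from 35.8 ± 3.22 to 19.9 ± 1.2 CPM (list median -0.33, camera adjusted p = 0.0205, or adjusted p = 0.439 with an estimated correlation). The camera call of the CDK inhibitors was lost without knockout-labelled replicate 4 (adjusted p = 0.108, range 0.00441 to 0.108 over the settings tried). All these genes lost their limma call in some test: Rrm2 without control replicate 1 or knockout-labelled replicate 1, 2 or 4 (adjusted p up to 0.0712), Fen1 without control replicate 1 or 3 or knockout-labelled replicate 1, 2, 3 or 4 (up to 0.0949), and Pole, Cdc45 and H2ax without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 4 (up to 0.15). Cdkn2c lost it without control replicate 1 (adjusted p = 0.0563).

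**Figure D3:**
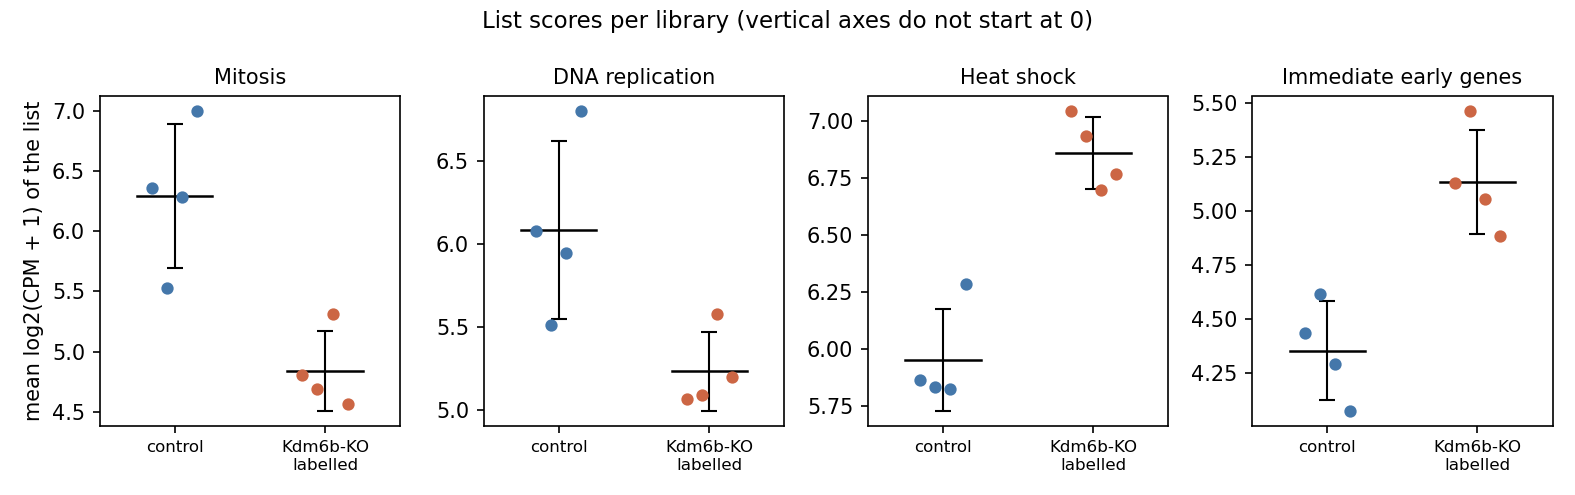
List scores, the mean log2(CPM + 1) of the tested members of a list, on the vertical axes for the 4 control and 4 knockout-labelled libraries; each point is a library, the long bar is the mean and the whiskers are the SD. Mitosis scores were 6.29 ± 0.60 in the controls and 4.84 ± 0.33 in the knockout-labelled libraries with no overlap, and heat shock and immediate early scores lay the other way.

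Some heat shock and immediate early genes rose, and 0 of either list fell. In the heat shock list 6 of 13 members rose and 7 were not called, and 6 rose adjusted over the list alone (median log2 change 0.50). Dnaja1, which encodes a co-chaperone of HSP70 proteins, rose from 332 ± 38.9 to 779.7 ± 186 CPM (log2 change 1.21 ± 0.16, limma adjusted p = 0.00434), and the chaperone gene Hsph1 from 34.7 ± 3.55 to 75.3 ± 19.0 CPM. Hspa1b was at 0.0409 ± 0.0530 and 9.22 ± 8.08 CPM, its control mean under the floor of detection. It was uneven too, at 18.5 and 13.4 against 2.78 and 2.13 CPM in knockout-labelled replicates 1 and 2 against 3 and 4, with a mean of 6.12 CPM without knockout-labelled replicate 1, and the control mean was 0.0175 CPM without control replicate 4. The camera adjusted p was 6.48e-07, or adjusted p = 0.162 with an estimated correlation. Of 17 immediate early genes, which respond to stimuli within minutes, 5 rose, or 7 adjusted over the list alone (median log2 change 0.59). Besides Jun and Fos they included Zfp36, which encodes an mRNA-destabilising protein, from 528 ± 100.2 to 871 ± 94.3 CPM, and the transcription factor gene Klf4, from 0.697 ± 0.391 to 3.49 ± 1.43 CPM. The camera adjusted p was 1.45e-07, or adjusted p = 0.404 with an estimated correlation. Called heat shock members numbered 3 without control replicate 1 and 3 without knockout-labelled replicate 2. Called immediate early genes numbered 1 and 2 without control replicates 1 and 3, and 2 and 3 without knockout-labelled replicates 1 and 3. Without knockout-labelled replicate 2 limma called 0 of them, with 7 at an unadjusted p below 0.05. Hspa1b lost its call without control replicate 1 or knockout-labelled replicate 2 (adjusted p up to 0.0667), Zfp36 without control replicate 1 or 3 or knockout-labelled replicate 1, 2, 3 or 4 (up to 0.0908) and Klf4 without control replicate 1 or 3 or knockout-labelled replicate 1 or 2 (up to 0.0877).

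Of 15 NOTCH1 targets 1 rose, or 2 adjusted over the list alone, with 5 at an unadjusted p below 0.05. Over all genes it was Hey1, from 7.13 ± 3.56 to 35.8 ± 17.5 CPM, whose call was lost without control replicate 1 or knockout-labelled replicate 2 or 4 (adjusted p up to 0.0615). The 5 genes went both ways, and 9 members of the list were higher and 6 lower. Named after their values were seen, Hes1 was at 45.9 ± 13.8 and 76.0 ± 21.4 CPM and Dtx1 at 979 ± 114 and 1218 ± 146 CPM. Myc was lower, at 117 ± 118 and 37.1 ± 10.3 CPM, with a control mean of 59.0 CPM without control replicate 4. The list was not called by camera (adjusted p = 0.0989, range 0.00620 to 0.305 over the settings tried), but it was with array weights (adjusted p = 0.00727) and without control replicate 4 (adjusted p = 0.00775) or knockout-labelled replicate 3 (adjusted p = 0.0407). The mixed fry test called the list (adjusted p = 0.0152) and the directional fry test did not (adjusted p = 0.563). In the T lineage list 1 of 19 fell, and 1 adjusted over the list alone, with 4 at an unadjusted p below 0.05. It was Ets1, a transcription factor gene of lymphoid cells, from 2130.3 ± 403 to 996 ± 177 CPM (log2 change -1.09 ± 0.19, limma adjusted p = 0.0145), and its call was lost without control replicate 1 (adjusted p = 0.0590). Camera did not call the list (adjusted p = 0.267), nor did directional fry (adjusted p = 0.686), while mixed fry did (adjusted p = 0.00951). Of 18 genes of double-positive thymocytes limma called 0, with 4 at an unadjusted p below 0.05 and 1 higher adjusted over the list alone (camera adjusted p = 0.650). Among them Cd1d1 was at 178 ± 44.6 and 285 ± 23.5 CPM and Endou at 816 ± 110.2 and 601 ± 65.8 CPM. The T cell activation and checkpoint list was higher by camera (adjusted p = 6.62e-05, or adjusted p = 0.439 with an estimated correlation). Of its 14 members limma called 0, with 5 at an unadjusted p below 0.05 and 3 higher adjusted over the list alone. Its scores overlapped between the groups, at 3.52 to 4.26 in the controls and at 4.05, 4.19, 5.20 and 4.52 in knockout-labelled replicates 1 to 4. Knockout-labelled replicate 3 also had the highest NK (4.69), B cell (4.19) and platelet (2.80) marker scores of the 8 libraries, and without it the camera adjusted p of the T cell activation list was 0.00280. The checkpoint receptor gene Lag3 was at 33.3 ± 11.9 and 74.2 ± 27.1 CPM and the costimulatory receptor gene Icos at 13.7 ± 0.980 and 22.3 ± 6.04 CPM.

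In the BCL2 family and the stress response list the called genes rose, while 3 signalling and chromatin lists each held 1 called gene in either direction. In the BCL2 family 2 of 15 rose: Bcl2, which blocks cell death, from 41.0 ± 3.84 to 69.0 ± 7.53 CPM, and its relative Bcl2a1d, from 3.99 ± 1.62 to 12.2 ± 4.33 CPM, a value made uncertain by near-identical copies. Adjusted over the list alone, 2 rose and 1 fell. In the unfolded protein and integrated stress response list 2 of 22 rose, and 2 adjusted over the list alone. They were the asparagine synthetase gene Asns, from 0.694 ± 0.478 to 3.84 ± 1.23 CPM, which lies on chromosome 6 from 7675169 to 7693254 among the called genes crowded there, and Ppp1r15a, which encodes a phosphatase subunit that restores translation after stress, from 45.3 ± 11.1 to 117 ± 46.2 CPM. Of 17 PI3K and mTOR genes the glucocorticoid-induced gene Tsc22d3 fell from 201 ± 72.4 to 72.2 ± 9.24 CPM and the phosphatase gene Inpp4b rose from 21.7 ± 9.29 to 51.5 ± 13.9 CPM, with the same numbers adjusted over the list alone. Of 12 genes of the H3K27 methylation machinery the X-linked gene Kdm6a rose and the Polycomb accessory gene Phf19 fell from 10.1 ± 2.74 to 4.69 ± 0.647 CPM, also with the same numbers adjusted over the list alone. For Kdm6a, sex and label cannot be told apart. Of 18 cytokine signalling genes the feedback inhibitor gene Socs2 rose from 0.267 ± 0.131 to 1.44 ± 0.146 CPM and the interferon gamma receptor gene Ifngr1 fell from 592 ± 178 to 294 ± 57.0 CPM, and adjusted over the list alone 2 rose and 1 fell. These lists were not called by camera, with adjusted p of 0.295, 0.522, 0.326, 0.493 and 0.588 in the order given. The mixed fry test called all of them (adjusted p = 0.00951, 0.0261, 0.0274 and 4.37e-06) except the stress response list (adjusted p = 0.0753), and the directional fry test called 0 of the 5. Apart from Tsc22d3, the calls depended on single libraries. Bcl2 lost its call without control replicate 1 or knockout-labelled replicate 2 (adjusted p up to 0.0654), Bcl2a1d without control replicate 1 or 3 or knockout-labelled replicate 2, 3 or 4 (up to 0.120), Asns without control replicate 1 or knockout-labelled replicate 2 or 4 (up to 0.0589) and Ppp1r15a without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 4 (up to 0.0962). Inpp4b lost it without control replicate 3 or knockout-labelled replicate 1, 2 or 3 (up to 0.107), Socs2 without control replicate 1 or 3 or knockout-labelled replicate 1, 2, 3 or 4 (up to 0.0946), Kdm6a without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 3 (up to 0.120), Phf19 without any library other than control replicate 2 (up to 0.117) and Ifngr1 without any library other than control replicate 4 (up to 0.138).

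Among interferon response genes 1 was called higher and 1 lower, and 25 were not called. Of 27 tested, the guanylate-binding protein gene Gbp2 rose from 46.7 ± 5.23 to 82.5 ± 26.3 CPM and Ifit2, which encodes an RNA-binding antiviral protein, fell from 28.7 ± 2.29 to 17.6 ± 4.08 CPM. Adjusted over the list alone, 5 rose and 1 fell. The list was higher by camera (adjusted p = 0.0473, or adjusted p = 0.820 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.466) and without knockout-labelled replicate 2 (adjusted p = 0.153) or 3 (adjusted p = 0.366). It was lost too under median-ratio scaling (adjusted p = 0.0581), quantile normalization (adjusted p = 0.0570), a pseudocount of 5 (adjusted p = 0.0521) and eBayes without trend (adjusted p = 0.0818), and its range over the settings tried was 0.00161 to 0.466. Gbp2 lost its call without any library other than control replicate 4 (adjusted p up to 0.143), and Ifit2 without control replicate 1, 2 or 3 or knockout-labelled replicate 1, 2 or 4 (up to 0.138).

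In 9 other pathway lists limma called 0 members and camera did not call the list. The MYC and ribosome biogenesis list had 1 of 22 members at an unadjusted p below 0.05 (camera adjusted p = 0.884), with Cad at 26.9 and 11.7 CPM and Pa2g4 at 214 and 142 CPM in controls and knockout-labelled libraries. For p53 targets these numbers were 3 of 18 (adjusted p = 0.493). The directional fry test called that list lower (adjusted p = 0.0441, median log2 change -0.08) and the mixed fry test did not (adjusted p = 0.497), with Ei24 at 13.7 and 7.23 CPM and Zmat3 at 18.5 and 13.7 CPM. The oxidative stress list had 3 of 16 (adjusted p = 0.493), with Txnrd1 at 50.6 and 37.0 CPM and Cat at 159 and 135 CPM. Among NF-kB targets there were 3 of 17 (adjusted p = 0.242), with Nfkbie at 80.6 and 54.6 CPM and Nfkbiz at 30.0 and 48.9 CPM. Mature T cell genes had 4 of 13 (adjusted p = 0.522) and migration genes 3 of 18 (adjusted p = 0.812), with Klf2 at 5.56 and 3.0 CPM and Selplg at 353 and 264 CPM. In glycolysis there were 8 of 19 (adjusted p = 0.295), with Hk1 at 147 and 112 CPM and Pfkm at 29.4 and 22.0 CPM. Oxidative phosphorylation had 4 of 24 (adjusted p = 0.293), with Uqcrfs1 at 165 and 124 CPM and Atp5a1 at 888 and 700.4 CPM, and cholesterol synthesis 3 of 19 (adjusted p = 0.0765), with Hmgcs1 at 51.7 and 35.1 CPM. Adjusted over the list alone, 1 NF-kB target and 2 migration genes fell and 0 changed in the other 7 lists. In the MYC list 10 members were higher and 12 lower, so Cad and Pa2g4 do not stand for the list. Its scores were 5.72, 5.54, 5.52 and 6.60 in control replicates 1 to 4. In knockout-labelled replicates 1 to 4 they were 5.61, 5.72, 5.89 and 5.88. Camera called the MYC list without control replicate 4 (adjusted p = 0.000503), oxidative phosphorylation without knockout-labelled replicate 4 (adjusted p = 0.0173), and cholesterol synthesis without control replicate 2 (adjusted p = 0.00813) or knockout-labelled replicate 2 (adjusted p = 0.0222) or 3 (adjusted p = 0.0173). Over the settings tried these adjusted p ranged from 0.000503 to 0.972 for MYC, 0.0173 to 0.601 for oxidative phosphorylation and 0.00813 to 0.810 for cholesterol synthesis. The haematopoietic progenitor list had 4 tested members, too few for the list test, with Lyl1 at 3.45 ± 1.17 and 2.05 ± 0.441 CPM and Kit at 0.985 ± 0.832 and 3.44 ± 4.22 CPM, its second mean 1.37 CPM without knockout-labelled replicate 3.

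Camera called 10 of the 33 lists, 5 higher and 5 lower. Scores overlapped between the groups in 5 of these, the DNA replication, DNA damage repair, interferon, T cell activation and mitochondrial lists. With an estimated correlation it called 0, with 3 lists at an unadjusted p below 0.05. The directional fry test called 6 lists and the mixed fry test 16. By directional fry these were the mitosis, p53 and immediate early lists (adjusted p = 0.0441 each), heat shock (0.0397), CDK inhibitors (0.0496) and the sex-linked genes (3.30e-06). At least 10 lists were called in 25 of the 35 splits of the libraries into 4 and 4, with 17 as the highest of the other splits, so the number of lists does not set the real groups apart from other groupings. Median, mean and camera direction differed in sign for the MYC, stress response, cytokine, double-positive thymocyte, myeloid, dendritic and ribosomal lists, and median and mean for the progenitor list.

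Markers of other blood cells did not pass the tests. Camera called 0 of the 5 marker lists large enough for it, and limma called 0 of their members, with 6 myeloid, 0 erythroid, 1 B cell, 2 NK and cytotoxic and 0 dendritic genes at an unadjusted p below 0.05 and 0 in each adjusted over the list alone. Their camera adjusted p were 0.460, 0.822, 0.0765, 0.293 and 0.839. Camera called the B cell list without control replicate 4 (adjusted p = 0.0196) or knockout-labelled replicate 1 (adjusted p = 0.0195), and the NK list without the latter (adjusted p = 0.0397). Over the settings tried the adjusted p ranged from 0.00665 to 0.149 for the B cell and 0.0397 to 0.967 for the NK list. Of the 6 myeloid genes at an unadjusted p below 0.05, named after their values were seen, 3 had higher means in the knockout-labelled libraries. S100a8 was at 10.7 ± 5.44 and 38.5 ± 28.5 CPM, S100a9 at 4.79 ± 2.49 and 20.2 ± 15.4 CPM, with no overlap between the groups, and Lcn2 at 3.01 ± 1.58 and 6.86 ± 4.07 CPM. The other 3 had lower means, with Itgam at 31.4 ± 8.14 and 22.0 ± 1.67 CPM, Csf1r at 15.8 ± 9.34 and 7.25 ± 4.04 CPM and Mpo at 3.90 ± 2.55 and 1.05 ± 1.60 CPM. The most abundant myeloid markers Cst3 and Lyz2 were at 95.6 ± 6.97 and 101 ± 13.0 CPM and at 88.1 ± 65.9 and 59.1 ± 23.9 CPM in controls and knockout-labelled libraries. Of the erythroid genes, Bpgm was at 132 ± 21.3 and 140.0 ± 14.2 CPM and the globin gene Hba-a2, with a near-identical copy, at 138 ± 171 and 125 ± 128 CPM. The B cell genes Ighm and Cd79b were at 745 ± 78.1 and 823 ± 19.6 CPM and at 13.8 ± 2.25 and 16.1 ± 3.56 CPM. Of the cytotoxic genes, Gzma was at 121 ± 98.8 and 60.2 ± 27 CPM and Prf1 at 74.3 ± 9.68 and 96.9 ± 17.2 CPM. The antigen presentation genes Cd74 and H2-Ab1 were at 186 ± 135 and 163 ± 88.0 CPM and at 42.5 ± 29.2 and 32.7 ± 14.5 CPM. Of the platelet list, too small for the list test, Itgb3 was at 3.63 ± 2.54 and 5.52 ± 5.29 CPM and Itga2b at 1.23 ± 0.841 and 1.83 ± 0.398 CPM. Several of these means moved by over 1.5 times with 1 library left out. In the controls, Lyz2, Hba-a2 and Cd74 were at 55.7, 53.8 and 121 CPM without replicate 2, and Gzma and Itgb3 at 71.7 and 2.37 CPM without replicate 4. In the knockout-labelled libraries, Mpo was at 0.254 CPM without replicate 1, Itgb3 at 2.91 CPM without replicate 3, and S100a8, S100a9 and Hba-a2 at 25.4, 13.1 and 61.8 CPM without replicate 4.

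Mitochondrially encoded genes were higher as a list (median log2 change 0.205, camera adjusted p = 0.0182, or adjusted p = 0.820 with an estimated correlation). Of 13 members limma called 0, with 5 at an unadjusted p below 0.05 and 1 higher adjusted over the list alone. Mitochondrial transcripts held 1.34% to 1.51% of the CPM in the controls and 1.49% to 1.74% in the knockout-labelled libraries. The list call was lost without control replicate 2 (adjusted p = 0.0873), control replicate 3 (adjusted p = 0.111) or knockout-labelled replicate 4 (adjusted p = 0.108, range 0.000325 to 0.111 over the settings tried). The cytochrome oxidase gene mt-Co1 was at 2694 ± 177 and 2644 ± 264 CPM and the ATP synthase gene mt-Atp6 at 1739.8 ± 95.1 and 2144 ± 166 CPM. Of 30 ribosomal protein genes limma called 0, with 1 at an unadjusted p below 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.812, or 1.07e-05 without control replicate 4, range 1.07e-05 to 0.967 over the settings tried). Among them Rps9 was at 1208 ± 271 and 1257 ± 157 CPM and Rps14 at 1225 ± 469 and 1056 ± 198 CPM. The ribosomal list scores were 7.64, 7.46, 7.49 and 8.46 in control replicates 1 to 4. In knockout-labelled replicates 1 to 4 they were 7.60, 7.68, 7.67 and 8.02.

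Called genes were crowded at the start of chromosome 6, a region chosen after its values were seen. In its first 10 Mb limma called 8 of 27 tested genes, 3 higher and 5 lower, Asns of the stress response list among the former, with an adjusted p of 0.000723 over 273 windows of that size (hypergeometric test, one-sided). That test treats neighbouring genes as independent. Pon2, which encodes a paraoxonase, rose from 64.1 ± 0.607 to 119 ± 9.58 CPM (log2 change 0.87 ± 0.10, limma adjusted p = 0.00198). Mios, a gene of the nutrient-sensing GATOR2 complex, fell from 32.1 ± 2.01 to 13.7 ± 2.19 CPM (log2 change -1.18 ± 0.15, adjusted p = 0.00339) and Umad1 from 12.4 ± 1.37 to 5.21 ± 1.52 CPM. The call of Umad1 was lost without control replicate 1 or 3 or knockout-labelled replicate 1 or 2 (adjusted p up to 0.0667), and those of Pon2 and Mios held with each single library left out (adjusted p up to 0.0241).

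**Figure D4:**
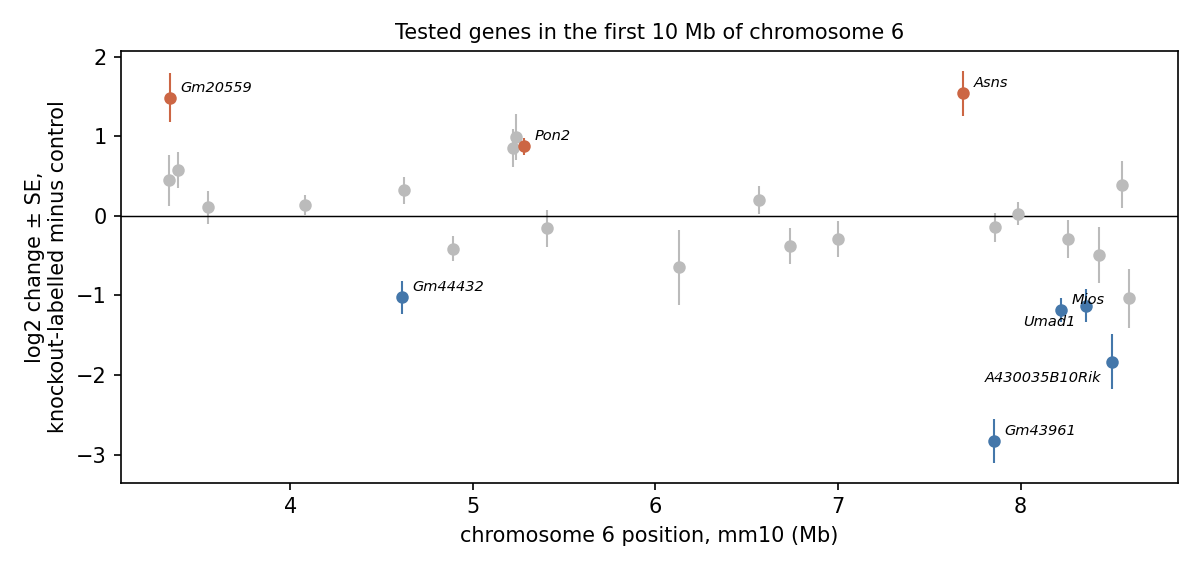
Log2 change, knockout-labelled minus control, with limma SE as whiskers on the vertical axis against position in Mb (mm10) on the horizontal axis for the 27 tested genes in the first 10 Mb of chromosome 6. Orange points are the 3 genes called higher, blue points the 5 called lower, and grey points were not called.

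All 218 genes in the authors' deposited table of changes above 2-fold were called by limma in the same direction. The authors' deposited table lists 168 genes as higher in control and 50 as higher in knockout, and 205 of the 218 were also at least 2-fold on the log2(CPM + 1) scale. Another 270 genes were called by limma but are not in the authors' deposited table, 84 of them at least 2-fold. Both used the same libraries, so the overlap is not independent evidence. In the authors' deposited table the highest knockout-over-control folds were those of Xist, Tsix and BC018473, and the highest control-over-knockout folds those of Ddx3y, Eif2s3y and Uty. BC018473, on chromosome 11 from 116752167 to 116759373, rose from 4.30 ± 2.61 to 179 ± 23.2 CPM (log2 change 5.24 ± 0.34, limma adjusted p = 9.17e-06).

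In no library did a single T cell receptor beta variable segment hold most of the Trbv CPM. Trbv19 or Trbv13-2 led in all 8 libraries. The leading segment held 12.0%, 11.5%, 12.7% and 24.1% in control replicates 1 to 4 and 12.2%, 12.2%, 12.0% and 14.6% in knockout-labelled replicates 1 to 4. In control replicate 4 Trbv13-2 led with 24.1%, Trbv1 followed with 15.6% and Trbv19 held 3.81%.

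Control replicate 4 stood apart from the other controls. Its Pearson correlation with them across genes, which are not independent replicates, was at most 0.968, while control replicates 1 to 3 correlated at 0.984 or more with each other. Knockout-labelled libraries correlated at 0.971 to 0.984 with each other. The first principal component (39.9% of the variance) put all 4 knockout-labelled libraries on one side and all 4 controls on the other, and the second held 22.5%. In a test without both libraries numbered 4, chosen after the data were seen, limma called 713 genes, 20 mitosis members, 7 heat shock members and 6 immediate early genes.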

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

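The tests of explanations and the counts over splits of the libraries were chosen only after the results were seen. A library is listed where its gap to the nearest of the other 3 in its group, divided by the group's whole range and taken on log2(CPM + 1) for genes, exceeded Dixon's critical value for 4 samples. This held for 17 of 248 groups checked, and chance gives about 12.4.

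Of these, 8 concern control replicate 4. Its Y-linked genes were low, with Eif2s3y at 110.0 CPM (others 131 to 136), Uty at 49.8 CPM (others 79.6 to 81.9) and Kdm5d at 22.9 CPM (others 43.5 to 47.1). Its Kdm6a was at 36.0 CPM (others 50.7 to 53.6), and its Tsix was high at 2.16 CPM (others 0 to 0.172). The ribosomal protein genes Rps9 and Rps14 were high at 1612 CPM (others 1043 to 1114) and 1929 CPM (others 962 to 1021). Its heat shock list score was 6.28 (others 5.82 to 5.86). In knockout-labelled replicate 4, Kdm6b was low at 451 CPM (others 618 to 656), Kdm6a low at 62.0 CPM (others 84.2 to 87.9) and Cdk5rap1 high at 58.9 CPM (others 25 to 28.6). Hspa1a was high in control replicate 2 at 0.477 CPM (others 0 to 0.0252), and Tsc22d3 in control replicate 3 at 309 CPM (others 161 to 172). In knockout-labelled replicate 2, Tbc1d2 was high at 73.3 CPM (others 44.8 to 48.2) and Lyl1 at 2.71 CPM (others 1.78 to 1.86). Pole was high in knockout-labelled replicate 3 at 11.9 CPM (others 5.78 to 6.42), and mt-Co1 in knockout-labelled replicate 1 at 3037 CPM (others 2479 to 2562).

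Mitosis genes were lower in the knockout-labelled libraries, with a median log2 change of -1.49. A single library as the cause is argued against, since the median was still -1.23 without control replicate 4, the loss that moved it closest to 0. Non-dividing cells that lack thymocyte genes are argued against as well, since they would lower the thymocyte list that the blasts express. The median of that list was -0.0107 (bootstrap interval over genes -0.09 to 0.09). The interval does not measure the spread between libraries, whose list scores ran from 8.83 to 9.75 in the controls and 9.29 to 9.68 in the knockout-labelled libraries. Non-dividing T cells that express these genes need not lower the list, so the test does not cover them. The sex of the mice and the label cannot be told apart, because 0 libraries differ from their group in Xist and Ddx3y. A change in cell division that follows the Kdm6b label therefore stays a hypothesis beside sex and non-dividing T cells that express thymocyte genes.

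Heat shock and immediate early genes were higher in the knockout-labelled libraries, with a median log2 change of 0.54 over both lists. A single library is argued against as the cause, since the median was 0.46 without knockout-labelled replicate 2, the loss that moved it closest to 0, but leaving out both knockout-labelled replicates 1 and 2 was not tested, and Jun, Fos, Hspa1a and Hspa1b were higher in these than in replicates 3 and 4 (for Jun 274 and 268 against 98.7 and 43.1 CPM). Longer handling before lysis may raise the same genes: 15 of 17 immediate early genes had a higher mean in the knockout-labelled libraries. Handling and a change in the cells cannot be told apart, because the labels give no handling times. The Kdm6b label and the sex of the mice both stay open as well.

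Called genes crowd the start of chromosome 6. A chance cluster is argued against if neighbouring genes are independent, since the permutation p for the most crowded window was 0.0002 over 10000 shuffles. Among the called genes, Gm44432, Gm43961 and A430035B10Rik lie within the span of Casd1, C1galt1 and Gm45062. Without a stated strand setting their reads may not be separable from those of these genes. A change in copy number of the whole region would move its genes one way together by more than 0.5. It is argued against too, as they had a median log2 change of -0.14 (bootstrap interval -0.41 to 0.32). A change of a smaller part may not move this median and was not tested. The called-lower genes Gm43961, Mios, Umad1 and A430035B10Rik lie between 7853871 and 8510430. C1galt1, Gm9825, Rpa3, Gm45062 and Glcci1 lie among or overlap them and were not called (log2 change -0.14, 0.03, -0.29, -0.50 and 0.39). A chromosome segment of another strain may give called genes in both directions, and 3 of the 8 called genes were higher. It cannot be told apart from other causes, because the labels used here give no strain per sample and reads were not analysed here.

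Over the 35 splits of the 8 libraries into 4 and 4, chance is argued against for the count of called genes. This holds only if the libraries are independent samples, which the labels do not say. The real groups gave 488 and the highest other split 1, and 1 split, the real one, gave a count as large. A share of 1 in 35 is the lowest that these splits can give, and they were chosen after the results were seen. Chance is therefore not excluded. Every other split mixes both labels and both sexes, so this does not bear on what sets the groups apart. On the same condition and with the same limits, chance is argued against for the genes changed at least 2-fold (289 against 1). Called members of the mitosis (23 against 0), heat shock (6 against 0) and immediate early lists (5 against 0) were also most numerous in the real groups. These 3 lists were chosen after the results were seen, so the splits cannot exclude chance for them. An exact permutation test of each list score gave p = 0.0286, the lowest it can give, and adjusted p = 0.143 over the 35 lists. Without knockout-labelled replicate 2 the called members of these lists numbered 1, 3 and 0. For the count of lists called by camera chance cannot be excluded: the real groups gave 10, the highest other split 17, and 25 of 35 splits gave as many.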

How the results depend on the processing

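Chosen only after the data were seen were the tests without the X and Y chromosomes and without both libraries numbered 4, and the counts of called members. The 488 called genes became 1313 with array weights and 1008 at an adjusted p under 0.1, the latter from its looser threshold. They ranged from 81 to 670 with 1 library left out. The 289 genes at 2-fold or more became 165 with a pseudocount of 5, which shrinks changes of low genes, and ranged from 71 to 395. Called members ranged from 1 to 26 for mitosis, 3 to 8 for heat shock and 0 to 5 for immediate early genes, with 8 of the last under array weights. The 10 called lists became 0 with an estimated correlation (3 at an unadjusted p below 0.05) and 6 with fry. The median leading share of Trbv segments was 12.2%, and that of Trav segments 5.07%. Array weights also called the NOTCH1 (0.00727), MYC (0.0272), B cell (0.0272) and ribosomal lists (0.0252) by camera adjusted p, and the test with no filter the cholesterol (0.0239) and B cell lists (0.00665). For array weights, the missing filter, the estimated correlation, fry and the left-out libraries beyond their smaller number, the cause was not tested.

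The Kdm6b change stayed above 0 and uncalled under every alternative, from 0.01 without control replicate 4 to 0.34 without knockout-labelled replicate 4. Of 49 called named genes, 0 changed sign, 31 lost the call with some library left out and 16 under some other alternative. Of 40 named genes not called, 11 gained a call under some alternative and 10 changed sign. On the log2 scale, mt-Co1 was at 0.00953 under quantile normalization, and with 1 library left out it ranged from -0.0977 to 0.00311. Over the same tests Lyz2 ranged from -0.70 to 0.0223, Bpgm from -0.0203 to 0.17, Hba-a2 from -0.45 to 1.05, Itgb3 from -0.13 to 0.67, Cd74 from -0.45 to 0.28, H2-Ab1 from -0.59 to 0.14, Rps9 from -0.0101 to 0.22 and Rps14 from -0.28 to 0.0745. Without both libraries numbered 4, Cst3 was at -0.00481 and Hba-a2 at -0.44. The cause was not tested.

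With the replicate block 509 genes were called, 392 of them shared with the 488, and by camera adjusted p the NOTCH1 list was called (0.0305) and the interferon list was not (0.0502). The deviations of same-numbered libraries from their group means correlated at 0.149, 0.0652, -0.102 and 0.176, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries. Depth differed between the groups, and a group mean under the floor of 3 reads was not detectable at this depth.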

Other observations

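The lists and genes of this part, and their tests, were all chosen only after the data were seen. Genes of chromosome segregation beyond the mitosis list were lower in the knockout-labelled libraries. Of 25 kinetochore and centromere genes 13 fell (median log2 change -1.11), of 10 mitotic kinesin genes 7 (median -1.36), and of 17 condensin and cohesion genes 9 (median -0.53), and 0 rose in any of them. Their camera adjusted p were 2.25e-14, 9.92e-10 and 2.11e-09 over the 5 added lists, or adjusted p = 0.0869 for each with an estimated correlation.

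Of 11 glucocorticoid receptor targets 3 fell: Tsc22d3, the receptor co-chaperone gene Fkbp5, from 270.3 ± 41.9 to 181 ± 8.77 CPM, and the kinase gene Sgk1, from 72.3 ± 16.5 to 41.7 ± 9.15 CPM (camera adjusted p = 0.0233, or adjusted p = 0.0869 with an estimated correlation). In the glutathione and xenobiotic conjugation list 3 of 14 rose and 1 fell (camera adjusted p = 0.276). The epoxide hydrolase gene Ephx1 rose from 17.7 ± 2.71 to 39.6 ± 10.46 CPM, Gstm7 from 4.48 ± 0.839 to 10.1 ± 2.77 CPM and Mgst1 from 9.59 ± 4.74 to 42.0 ± 23.6 CPM, while the glutathione synthetase gene Gss fell from 43.3 ± 10.7 to 24.1 ± 1.32 CPM. The growth arrest genes Gadd45a and Gadd45b rose from 10.4 ± 2.93 to 20.7 ± 3.94 CPM and from 5.21 ± 1.15 to 10.8 ± 2.81 CPM, and the Schlafen family genes Slfn5 and Slfn8 fell from 64.3 ± 15.0 to 21.5 ± 6.43 CPM and from 70.5 ± 7.70 to 42.4 ± 11 CPM. Apart from Slfn5 and Tsc22d3, these calls depended on single libraries. Sgk1 lost its call whichever library was left out (adjusted p up to 0.137), and Fkbp5, Gstm7, Gss and Gadd45a lost it without control replicate 1 or 3 or knockout-labelled replicate 1, 2, 3 or 4 (up to 0.125). Ephx1 lost it without control replicate 1 or 3 or knockout-labelled replicate 2 or 4 (up to 0.0663), Mgst1 without control replicate 1 or 3 or knockout-labelled replicate 1, 2 or 4 (up to 0.0599), Gadd45b without any library other than control replicate 2 (up to 0.140) and Slfn8 without any library other than control replicate 4 (up to 0.140).

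On chromosome 11, between 116739062 and 116843449, the neighbouring genes Gm11735, BC018473, St6galnac1 and Jmjd6 were all called higher. Gm11735 and St6galnac1 were listed at 0 in all 4 controls and were low in the knockout-labelled libraries, at 2.05 ± 0.953 and 1.37 ± 0.481 CPM. Jmjd6 rose from 70.1 ± 8.50 to 118 ± 7.12 CPM. The call of St6galnac1 was lost without control replicate 1 (adjusted p = 0.0589). On chromosome 18, Commd10 rose from 27.6 ± 3.45 to 57.6 ± 2.68 CPM (log2 change 1.04 ± 0.13, limma adjusted p = 0.00241), while its neighbours Ap3s1 and Atg12 were at 146 and 161 CPM and at 89.2 and 88.5 CPM and not called. Of the X-linked genes with a Y-linked partner, Kdm5c was at 103 ± 10.4 and 129 ± 17.0 CPM, Ddx3x at 257 ± 33.2 and 227 ± 10.52 CPM and Eif2s3x at 95.8 ± 16.2 and 95.7 ± 8.76 CPM in controls and knockout-labelled libraries, and limma called none of these 3, with Kdm5c at an unadjusted p of 0.0313. Kdm6a, the partner of Uty, was called higher (log2 change 0.73 ± 0.16, limma adjusted p = 0.0360). Within 20 Mb of Kdm6b 22 of 462 tested genes were called (4.76%), against 3.46% of genes elsewhere (Fisher's exact test, two-sided, p = 0.154). For the whole of chromosome 11, Fisher's exact test gave p = 0.00928 (adjusted p = 0.0681 over the chromosomes), with 53 of 1062 called (4.99%). For chromosome 15, Fisher's exact test gave adjusted p = 0.0681, with 30 of 520 called (5.77%). Dgkeos, Cyb561 and Kpna2, named above for their low changes, also lie on chromosome 11, from 89064729, 105933702 and 106988629. A segment linked to Kdm6b was not tested beyond these counts.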
